A study of Mus musculus with 6 samples.

How the data were processed

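RNA was sequenced from long-term haematopoietic stem cells (LT-HSC) of C57BL/6 mice, sorted as lineage-depleted, Sca-1 and Kit positive cells that were negative for CD34, CD48 and Flk2 and positive for CD150. Per the labels, 3 libraries came from mice homozygous for an Itpkb allele induced with the mutagen ENU and 3 from wild-type littermates. Each library was a separate pool of 4 mice with at least 10000 sorted cells, so the libraries of a genotype are separate biological samples. Per the labels' protocols, 1 to 5 ng of RNA was amplified with the NuGEN Ovation kit, which does not mark strand, so reads of a gene and of its antisense partner cannot be told apart.

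Per the submitters' processing notes, the reads went through CASAVA 1.8.2, cutadapt and TopHat2 2.0.8b against build mm10, with Partek and edgeR. The series design text instead gives TopHat 1.4.1 with Bowtie2 and Partek 6.6 annotation, and which of the 2 versions made the table is not given in the sources used here. The deposited table holds 23998 genes and 6 columns of a signal that the authors obtained by dividing gene counts by 1 factor per library. The values are on the scale of CPM and are called normalized CPM in the text. The 6 implied factors multiply to 1, as edgeR scales them. Every value was a whole multiple of 1 step per library: 100% lay within 0.01 read of a whole number of reads. The recovered totals were 4024203 to 7470329 reads, and TMM factors recomputed from them with edgeR 4.0.16 differed from the authors' by at most 5e-05. One read was worth 0.131 to 0.249 normalized CPM, and 3 reads, taken as the detection floor, 0.393 to 0.746. The reads carry no molecular identifiers, so this floor covers counting error only.

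The design fixed before the data were examined assumed counts, with limma on log values as the test for a table of CPM. Since the values are normalized, limma 3.58.1 (R 4.3.3) was used with a mean-variance trend on log2(value + 1), for genes with a value of at least 1 in at least 3 libraries. This kept 12008 genes. Fold changes are on this log2 scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p of at most 0.15, the false discovery limit in the series design text. The count at 0.05 is given beside it. The study's own limits add a fold above 1.4 and an average log2 CPM above 4. The robust edgeR quasi-likelihood test, planned as the main test for counts, became an alternative on the recovered reads after the data were seen. It tested 11486 genes and called 692, of which 622 were called by limma in the same direction.

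Gene lists were fixed before the data were examined: 21 of pathways, 10 of cell types and 1 of the sort gate. They were tested with camera from limma on the same log2 values, where the design had named voom values, with a preset inter-gene correlation of 0.01, and called at an adjusted p of at most 0.05. The list of mitochondrially encoded genes had 0 of 26 symbols in the table, which left 31 lists. Members were also adjusted over the list alone. The genes named in the text follow a rule set in advance: Itpkb, then the 10 largest increases and 10 largest decreases among genes within the study's limits whose libraries did not overlap, leaving out unnamed loci, and the 3 members of each list with the smallest p, and the 6 sort gate genes. Some list members are not reported here. Outside this rule, Hlf, Mecom, Prdm16, Kif11, Rbl2, Tespa1, Notch1, Mpo, Elane and S100a8, all list members, were chosen after their values were seen. Positions are those of GENCODE M21 on build mm10. Through current and older symbols, 99.1% of the tested genes had a length and GC content.

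The titles number the libraries 1 to 3 in both genotypes. Deviations from the genotype means correlated at 0.296, 0.268 and 0.284 between same-numbered libraries and at -0.048 or below between others, a check across genes. Because the values were centred on each genotype's mean, positive values between same-numbered libraries force negative ones between others. Part of the contrast is therefore arithmetic, and with few possible matchings of the numbers the check cannot exclude chance. By the criterion set for such data the numbers were taken as pairs, although no label says what a number stands for. The fit without the pairing was kept as the main one, as designed, and the fit with the replicate block is given where it changed a call or a count. Replicates were also compared for duplication: the chi-square per degree of freedom between libraries of a genotype ran from 5.9 to 25.2, so none repeated another.

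The test was tried on simulated counts drawn from the real means and library sizes, in 10 runs with 200 changed genes each. The changed genes were drawn only from genes with a mean above 4 normalized CPM, so recovery of lower genes was not measured. At 3 libraries against 3, it recovered 15.6% of genes changed 1.5-fold, 62.1% changed 2-fold and 97.2% changed 4-fold, and 16.4% of its calls were false against a limit of 15%. The simulated genes were independent of each other, so the run could not test how camera behaves with correlated genes, and its mean of 0.1 unchanged lists called does not carry over to them.

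Alternatives planned in advance were DESeq2 1.42.0 size factors and upper-quartile scaling of the recovered reads, other filters and a pseudocount of 0.5, the replicate block, leaving out each library, DESeq2 and edgeR count tests, an adjusted p limit of 0.05, a quasi-likelihood test that is not robust, and for lists an estimated correlation, fry and voom values. Alternatives added after the data were seen were the robust quasi-likelihood test on the recovered reads, robust variance moderation, leaving out both libraries numbered 1 or 2, the mean of the granulocyte list as a covariate (its own list was not scored there), the block with a correction for GC content and length, and the block with an estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.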

Results

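Itpkb encodes inositol-trisphosphate 3-kinase B, which converts inositol trisphosphate to inositol tetrakisphosphate. The series compared the transcriptomes of LT-HSC from Itpkb-/- mice with those of wild-type littermates, 3 libraries each. The recovered totals were 4777870, 6559673 and 7470329 reads in the Itpkb-/- libraries and 4024203, 6597505 and 5241831 in the wild-type libraries. Between 13378 and 13988 genes had at least 1 read per library, and the 10 most abundant genes took 4.76% to 5.67% of the signal.

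Itpkb itself (chromosome 1, 180330485 to 180424802, plus strand, build mm10) was measured at 10.2, 13.99 and 18.2 normalized CPM in the Itpkb-/- libraries and at 22.1, 23.6 and 25.1 in the wild-type libraries. The means were 14.1 ± 3.99 and 23.6 ± 1.5 (SD, n = 3 each), a log2 difference of -0.73 (SE 0.24). The difference did not pass the test (limma, adjusted p = 0.172) and passed it with the replicate block (adjusted p = 0.0541) and without knockout replicate 3 (0.118), in a range of 0.0541 to 0.508 over the alternatives. All 3 Itpkb-/- libraries lay below all 3 wild-type libraries. The allele is a point-mutagen allele whose transcript need not be lost, so its level checks the labels only in part.

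LT-HSC of the 2 genotypes differed in 661 of 12008 genes tested (limma, adjusted p of at most 0.15), 272 higher and 389 lower in Itpkb-/- cells. Among the largest increases within the study's limits were Plac8 (chromosome 5, 100553725 to 100572245, minus strand), from 58.5 ± 19.1 to 298.2 ± 100.5 normalized CPM (log2 difference 2.32, SE 0.28, adjusted p = 0.00346), and the tetraspanin Cd53, from 24.9 ± 5.28 to 104.1 ± 23.1 (log2 difference 2.02, adjusted p = 0.00227). Receptors of haematopoietic cytokines rose, among them Il1r1, the interleukin-1 receptor, by 1.89 on the log2 scale. Csf2rb, a beta subunit of the interleukin-3 and GM-CSF receptors, rose by 2.01, and Csf2rb2, a beta subunit of the interleukin-3 receptor, by 2.19. Csf2rb and Csf2rb2 are near-identical neighbours on chromosome 15, so how reads were divided between them is uncertain. Other large increases were in Ffar2 (log2 difference 2.29), a receptor of short-chain fatty acids, Selp (1.87), which encodes P-selectin, Pdgfrb (1.84), Fam46a (1.84) and Mt1 (1.83), a metallothionein.

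The largest decreases within the study's limits were in Hid1 (chromosome 11, 115347707 to 115367756, minus strand), from 76.3 ± 19.3 to 10.7 ± 5.45 normalized CPM (log2 difference -2.82, SE 0.36, adjusted p = 0.00494), Tenc1 (-2.45), Dlg2 (-2.33) and the proteoglycan gene Bgn (-2.13). Fgd5 (chromosome 6, 91978878 to 92076004, plus strand), a gene whose reporter marks mouse HSC, fell from 56.4 ± 9.33 to 15.3 ± 3.32 (log2 difference -1.83, SE 0.21, adjusted p = 0.00303). Klf12 (-1.84), Fhl1 (-1.78), Plxna4 (-1.58), Glis2 (-1.57) and Lhcgr (-1.52) also fell.

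**Figure D1:**
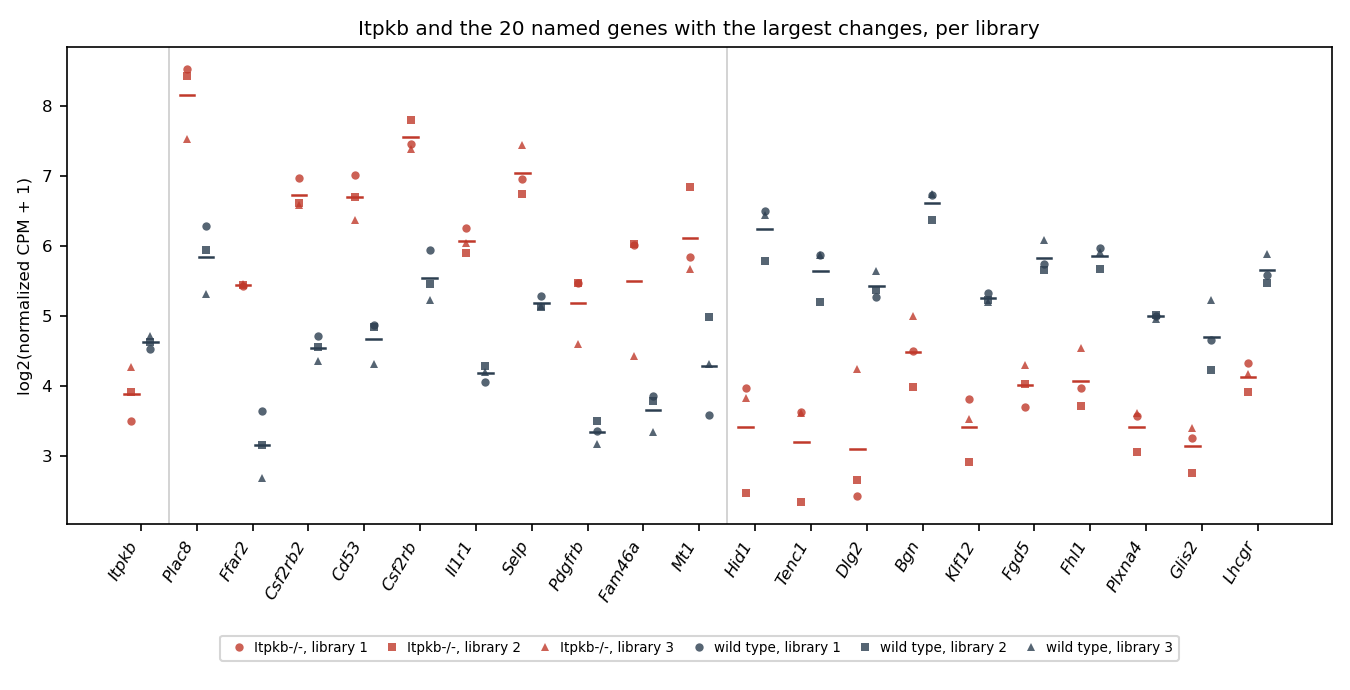
Normalized CPM on a log2(value + 1) axis for Itpkb and the 10 largest increases and 10 largest decreases named by rule, in 3 Itpkb-/- (red) and 3 wild-type (dark) libraries, with symbols for the library number and bars for the mean. Plac8 averaged 298.2 normalized CPM in Itpkb-/- against 58.5 in wild-type libraries, and Hid1 10.7 against 76.3.

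At an adjusted p of at most 0.05, the main fit called 182 genes, 74 higher and 108 lower. The fit with the replicate block called 1065 at that limit, 545 higher and 520 lower. Under the study's limits 387 genes remained with limma, 185 higher and 202 lower, where the series design text gives 441. The tests may differ, since the submitters' processing notes name edgeR. At the same limits the robust edgeR quasi-likelihood test on the recovered reads called 434 genes, 206 higher and 228 lower. The edgeR exact test on these reads called 554. The libraries of the genotypes did not overlap in 2562 genes, 21.3% of those tested against 10% by chance for exchangeable libraries, which leaves out the pairing of same-numbered ones. The count of 661 became 2176 with the replicate block (1099 higher, 1077 lower), which called all 661 in the same direction, and 856 genes under the study's limits. It was 74 without wild-type replicate 3, 266 without knockout replicate 2, 299 without wild-type replicate 1 and 297 without wild-type replicate 2. Of 73 named genes called, 28 kept their call whichever library was left out, and these include the 20 genes above except Fam46a, Mt1, Dlg2 and Glis2, whose adjusted p without wild-type replicate 3 was 0.209, 0.195, 0.162 and 0.200.

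Of 46 tested genes known from HSC, the stem cell list, 17 fell in Itpkb-/- LT-HSC, 1 rose and 28 did not pass, with a median log2 difference of -0.44, and adjusted over the list alone 32 fell and 2 rose. Besides Fgd5, Procr, the endothelial protein C receptor, fell from 56.5 ± 6.52 to 19.97 ± 5.49 normalized CPM (log2 difference -1.48, adjusted p = 0.00835). The transcription factor genes Hlf (-0.95), Mecom (-0.71) and Prdm16 (-0.70) fell as well. Clca1 was the member that rose, by 1.46, from 45.3 ± 2.34 to 127.4 ± 25.1. The list mean was lower in Itpkb-/- cells in all 3 same-numbered pairs. The list was called by camera (adjusted p = 8.32e-13), and the call was lost with an estimated correlation (adjusted p = 0.480). With the replicate block 30 members fell and 2 rose.

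All 34 tested genes of the G2/M phase had a positive log2 difference in Itpkb-/- LT-HSC, with a median of 0.58, and 4 rose: Cdk1 (0.76), the mitotic cyclin-dependent kinase, Cenpa (0.74), Ccnb1 (0.63) and Kif11 (0.61). Cdk1 was at 69.7 ± 19.3 normalized CPM against 40.3 ± 6.64 in wild type (limma, adjusted p = 0.113). Adjusted over the list alone 25 rose, and with the replicate block 28 rose. Without knockout replicate 2, which stands apart in granulocyte genes, the G2/M median was 0.34. Of 33 S-phase genes 3 rose, Tk1 (0.65), Prim1 (0.61) and Mcm7 (0.50), and 12 with the block, and adjusted over the list alone 6 rose. Camera called both lists (adjusted p = 1.89e-11 for G2/M and 3.96e-07 for S phase), and both calls were lost with an estimated correlation (adjusted p = 0.480 for each). The G2/M and S-phase genes named by rule each lost their call in at least 3 of the 6 fits without 1 library, where the highest adjusted p was 0.265 for Cenpa, 0.310 for Cdk1, 0.350 for Ccnb1, 0.324 for Mcm7, 0.306 for Prim1 and 0.386 for Tk1.

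Regulators of the entry into the cycle changed in both directions. Cdk6, a kinase that drives G1 progression, rose from 246 ± 2.06 to 536 ± 81.6 normalized CPM (log2 difference 1.11, SE 0.13, adjusted p = 0.00325). Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, fell from 23.7 ± 6.15 to 6.83 ± 2.74 (log2 difference -1.70, SE 0.32, adjusted p = 0.0320). Ccnd1, a D-type cyclin, fell by 0.83, and without 1 library its adjusted p reached 0.352. Cdkn1a, another cyclin-dependent kinase inhibitor gene of this list, rose from 7.76 ± 4.17 to 18.4 ± 5.39 (log2 difference 1.23, adjusted p = 0.135). Without 1 library its adjusted p reached 0.403. Of the 21 tested G0/G1 regulators 2 rose and 4 fell, and adjusted over the list alone, as with the replicate block, 4 rose and 5 fell. Camera did not call this list (adjusted p = 0.523).

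**Figure D2:**
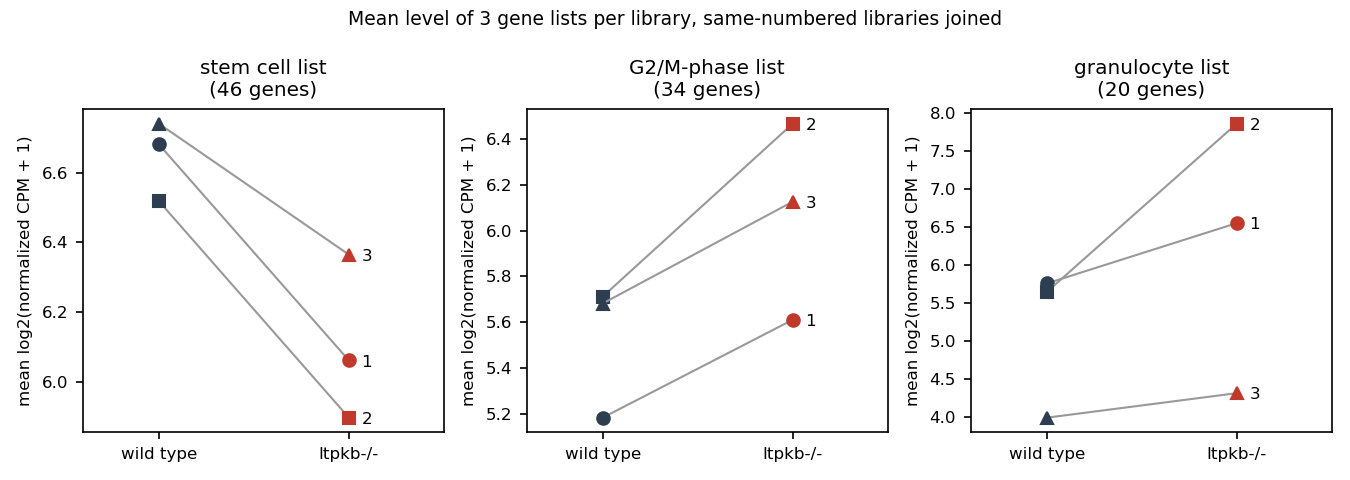
Mean log2(normalized CPM + 1) of the stem cell, G2/M-phase and granulocyte lists in each library, with same-numbered wild-type and Itpkb-/- libraries joined by a line. The stem cell mean was lower and the G2/M mean higher in Itpkb-/- libraries in all 3 pairs, and the granulocyte mean was highest, at 7.87, in Itpkb-/- library 2.

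Among 28 genes of the Atf4 and amino acid list 8 rose in Itpkb-/- cells and none fell, and adjusted over the list alone 13 rose and 2 fell. They include Asns, asparagine synthetase (37.2 ± 4.95 to 71.9 ± 5.97 normalized CPM, log2 difference 0.94, adjusted p = 0.0224), Slc7a5, a transporter of large neutral amino acids (0.76), and Aars (0.79), whose adjusted p was 0.163 without wild-type replicate 3. All 31 proteasome genes had positive log2 differences, with a median of 0.26, and 1 passed the test, Psma3 (0.51). One gene passed in each of the lists of ribosome biogenesis (Rrp9, 0.75, among 42), nuclear-encoded oxidative phosphorylation (Ndufa9, 0.45, among 77) and the unfolded protein response (Edem1, 0.61, among 29). Without 1 library the adjusted p of these 4 genes reached 0.278, 0.370, 0.331 and 0.414. None of the oxidative phosphorylation genes passed over the list alone (limma), though 7 had an unadjusted p under 0.05 and 1 was called by edgeR. Adjusted over the list alone (limma), 10 proteasome and 7 ribosome biogenesis genes rose, and in the unfolded protein response 2 rose and 1 fell. With the replicate block, 13 genes of the Atf4 list rose and 2 fell, 11 proteasome, 20 ribosome biogenesis and 13 oxidative phosphorylation genes rose, and 7 genes of the unfolded protein response rose and 3 fell. Camera called these 5 lists as higher, with adjusted p of 1.14e-06 for the Atf4 list, 3.24e-08 for the proteasome, 3.96e-07 for ribosome biogenesis, 2.91e-04 for oxidative phosphorylation and 0.0279 for the unfolded protein response. The first 4 calls were lost with an estimated correlation at adjusted p = 0.480 and the last at adjusted p = 0.558. The unfolded protein response call was also lost without knockout replicate 2 (adjusted p = 0.302) without wild-type replicates 2 and 3 (0.0854 and 0.0688), without both libraries numbered 2 (0.502), with the expression limit applied before testing (0.0620) and with the granulocyte mean as a covariate (0.220), and the oxidative phosphorylation call with the block and a GC and length correction (0.126).

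Of 32 targets of Foxo factors, 4 fell and 10 had positive log2 differences. Those that fell were Txnip (log2 difference -0.81), a glucose uptake inhibitor, Gabarapl1 (-0.64) and Ulk1 (-0.47), which act in autophagy, and Rbl2 (-0.44). Adjusted over the list alone 8 fell. Without 1 library the adjusted p reached 0.289 for Txnip, 0.361 for Gabarapl1 and 0.328 for Ulk1. None of the 23 sterol synthesis genes passed (limma), over all genes or over the list alone, or by edgeR, 1 had an unadjusted p under 0.05, and the median log2 difference was -0.28. With the block 8 genes of each list fell and 1 Foxo target rose. Camera called both (adjusted p = 0.0162 for Foxo targets and 0.0106 for sterol synthesis) and neither with an estimated correlation (adjusted p = 0.558 for each). The Foxo call was lost without knockout replicate 2 (0.131) and wild-type replicate 1 (0.150), and the sterol call without knockout replicate 3 (0.220) and wild-type replicate 1 (0.0933).

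**Figure D3:**
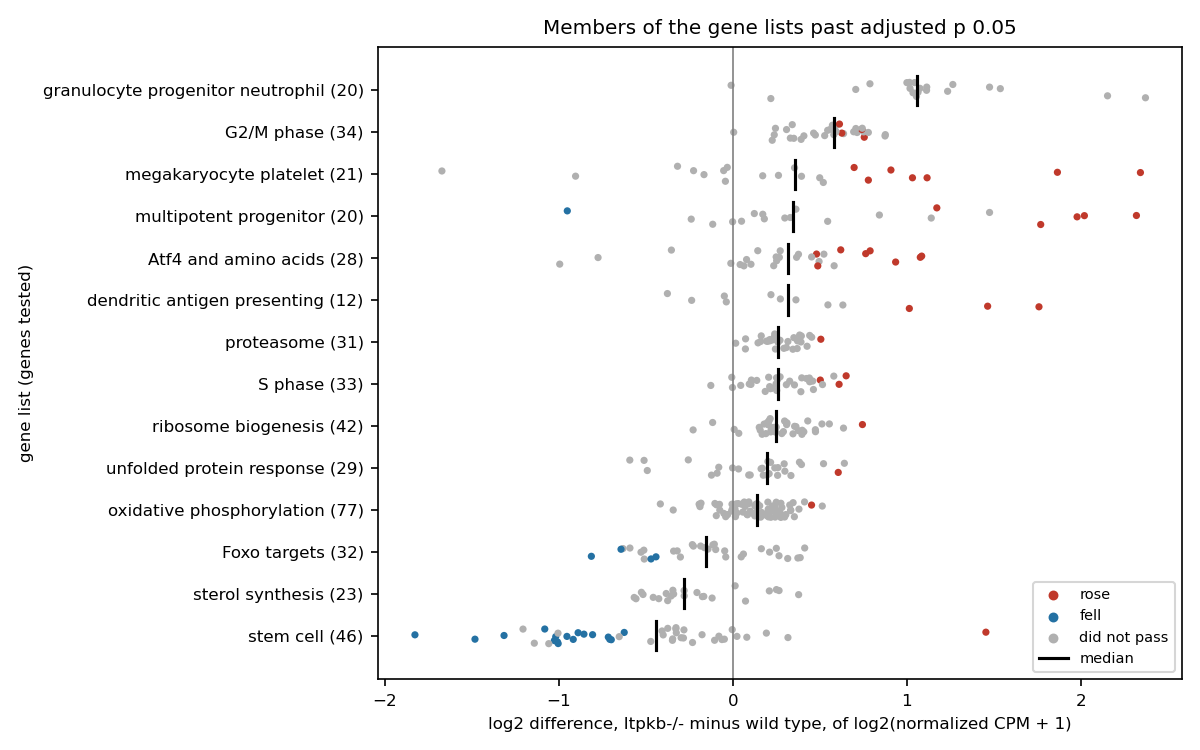
Log2 difference between Itpkb-/- and wild-type libraries for each tested member of the 14 lists called by camera, coloured by whether the gene rose, fell or did not pass, with black bars for the list medians. All 34 G2/M-phase genes lie above 0, and the stem cell list has its median at -0.44.

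Of 20 multipotent progenitor genes 5 rose in Itpkb-/- libraries and 1 fell. Plac8, Cd53, Wfdc17 (1.98) and Tespa1 (1.77) were among those that rose, and Notch1 fell by 0.95. Of 21 megakaryocyte and platelet genes 7 rose, among them Selp, Itga2b, which encodes the integrin CD41 (139.1 ± 8.89 to 307.4 ± 71.2 normalized CPM, log2 difference 1.12, adjusted p = 0.00831), and Plek (1.03). The mean of this list was lower in Itpkb-/- library 2 than in wild-type library 2, by a log2 difference of -0.0987, and higher in the pairs numbered 1 and 3 (0.528 and 0.648). In the dendritic and antigen-presenting list, 3 of 12 genes rose, and these were the MHC class II genes H2-Eb1 (1.76), H2-Ab1 (1.47) and H2-Aa (1.01), the last with an adjusted p of 0.194 without wild-type replicate 3. Adjusted over the list alone, 9 progenitor genes rose and 1 fell, 9 megakaryocyte genes rose and 3 fell, and 4 antigen-presenting genes rose. With the block 10 progenitor genes rose and 1 fell, 9 megakaryocyte genes rose and 3 fell, and 4 antigen-presenting genes rose. Camera called the 3 lists at adjusted p = 2.91e-04, 3.08e-04 and 0.00250. These calls were lost with an estimated correlation, at adjusted p = 0.480, 0.558 and 0.480.

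Primary granule genes of the granulocyte list were far higher in 1 Itpkb-/- library than in the other 5. Mpo, myeloperoxidase of granulocyte progenitors, was at 588, 8728 and 88.5 normalized CPM in Itpkb-/- libraries 1, 2 and 3 and at 263, 817 and 97.7 in wild-type libraries, and Elane was at 1303 in Itpkb-/- library 2. S100a8, a gene of mature neutrophils, was at 2132, 2232 and 207 in Itpkb-/- libraries 1, 2 and 3 and at 1149, 511 and 165 in wild-type libraries. None of 20 granulocyte genes passed the test (limma), over all genes or over the list alone, or by edgeR, 1 had an unadjusted p under 0.05, and 17 rose with the replicate block, among them Ctsg (log2 difference 2.37, adjusted p = 0.339 and blocked adjusted p = 0.00565). Camera called the list (adjusted p = 7.83e-04), and the call was lost with an estimated correlation (adjusted p = 0.572), without knockout replicate 2 (0.302) and without wild-type replicate 3 (0.123). The G2/M mean was also highest in Itpkb-/- library 2 and the stem cell mean lowest. Without this library the stem cell and G2/M lists were still called (adjusted p = 1.57e-09 and 6.37e-07), and with all 6 libraries neither was called with an estimated correlation (adjusted p = 0.480 for each). With the granulocyte mean as a covariate 186 genes were called.

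None of the 6 genes of the sort gate passed the test (limma), by edgeR or at an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 1 fell. Kit had a log2 difference of -0.30, Ly6a of -0.12 and Slamf1 of 0.02. The gate excludes the proteins of Cd34, Cd48 and Flt3. Cd34 was at 212.3 ± 8.21 normalized CPM in Itpkb-/- and 187.4 ± 15.8 in wild-type cells (log2 difference 0.18, adjusted p = 0.525). Cd48 and Flt3 were at 23.7 ± 14.5 and 28.9 ± 7.93 normalized CPM in Itpkb-/- and 9.07 ± 4.47 and 18.0 ± 12.4 in wild-type cells (log2 differences 1.14 and 0.84, adjusted p = 0.328 and 0.364). With the replicate block Cd48 (adjusted p = 0.0205), Flt3 (0.0569) and Kit (0.0600) passed the limit.

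In the list of inositol phosphate and calcium signalling, the pathway in which Itpkb acts, Nfatc2 (log2 difference -0.88) and Plcb2 (-0.44) fell and Plcg2 (0.45) rose, out of 36 genes tested. Adjusted over the list alone the same numbers passed, 1 higher and 2 lower, and with the block 1 rose and 5 fell. Without 1 library their adjusted p reached 0.189, 0.417 and 0.302, and camera did not call the list (adjusted p = 0.186). Among interferon response genes 6 of 41 rose, including Igtp (0.76) and Tap1 (0.63), and the list was not called (adjusted p = 0.105), but was called without knockout replicate 2 (0.0295), without wild-type replicate 1 (4.92e-04) and without both libraries numbered 1 (0.00273). The immediate early genes Socs3 (1.75) and Nr4a1 (1.46) rose and Jun fell by 0.82, and the list was not called (adjusted p = 0.217) but was called as lower without knockout replicate 1 (0.00606) and with the expression limit applied before testing (0.00940). Adjusted over the list alone 7 interferon genes rose and 2 fell, and 4 immediate early genes rose and 7 fell. With the block 10 interferon genes rose and 2 fell, and 4 immediate early genes rose and 8 fell. Without wild-type replicate 3 the adjusted p was 0.178 for Igtp, 0.264 for Tap1, 0.195 for Socs3, 0.207 for Nr4a1 and 0.206 for Jun. Ribosomal protein genes had a median log2 difference of -0.08, with none of 79 passing (limma), by edgeR or at an unadjusted p under 0.05, while 8 fell with the replicate block. Camera did not call them (adjusted p = 0.0974) but called them as lower with the replicate block (adjusted p = 0.00544), without knockout replicate 1 (2.26e-08), wild-type replicate 3 (0.00357) or both libraries numbered 1 (1.18e-06), with the expression limit applied before testing (0.0148), with the granulocyte covariate (0.00277) and with the block and the GC and length correction (3.28e-08). With an estimated correlation the adjusted p of ribosomal proteins was 0.841, and 0.554 with the block, that of the interferon list 0.645 and that of the immediate early list 0.823.

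The remaining lists were not called with all 6 libraries. Hmox1, haem oxygenase 1, fell from 9.59 ± 1.47 to 2.03 ± 0.53 normalized CPM, Gsta4 (log2 difference -1.16) and Srxn1 (-0.97) fell, in an oxidative stress list with adjusted p = 0.949. Ldha (0.47) and Eno1 (0.70) rose and Aldoc fell by 0.89 among glycolysis genes (adjusted p = 0.372). Cdkn1a rose by 1.23 and Plk2 fell by 2.06 among p53 targets (0.414), and Pik3cb rose by 0.69 among genes of the PI3K, Akt and mTOR pathway (0.446). No autophagy and lysosome gene passed (limma, list adjusted p = 0.801) or was called by edgeR, 1 higher and 1 lower gene had an unadjusted p under 0.05, and 1 rose and 2 fell with the replicate block. Of cell type lists, the adjusted p was 0.176 for endothelial and stromal genes, where Sparc (2.72) and Pdgfrb rose and Emcn fell by 1.46, and 0.203 for T and NK genes, where Thy1 rose by 1.27. Gzmb, of the same list, was at 3.58 ± 2.04 normalized CPM against 0 in all 3 wild-type libraries. The value was 0.433 for erythroid genes, where Rhag (1.67) and Epor (0.89) rose and Car2 fell by 0.63, 0.511 for the sort gate, 0.567 for monocytes and macrophages, 0.869 for mast cells, basophils and eosinophils, where Fcer1a rose by 1.64, and 0.978 for B-lymphoid genes. Adjusted over the list alone, 5 of 22 glycolysis genes rose and 4 fell, where 3 rose and 2 fell over all genes. These counts were 0 and 4 in both for oxidative stress, 1 and 1 in both for p53 targets, 1 and 0 in both for the PI3K pathway and for mast cells, and 2 and 1 in both for erythroid genes. For endothelial genes they were 3 and 1 against 2 and 1, and for T and NK genes 3 and 0 against 2 and 0. No monocyte or B-lymphoid gene passed either way (limma) or by edgeR, and 2 higher and 1 lower monocyte genes had an unadjusted p under 0.05. With the replicate block 3 monocyte genes rose and 1 fell, 5 erythroid genes rose and 5 fell, 3 oxidative stress genes rose and 4 fell, and 5 glycolysis genes rose and 4 fell. The block also called 2 p53 targets as higher and 2 as lower, 2 PI3K pathway genes as higher and 1 as lower, 2 mast cell and 3 T and NK genes as higher, 3 endothelial genes as higher and 1 as lower, and no B-lymphoid gene. None of these lists' genes named in this paragraph kept its call in all 6 fits without 1 library except Emcn and Pdgfrb, with a highest adjusted p of 0.152 for Hmox1 and up to 0.403 for Cdkn1a. Camera called erythroid genes as higher without knockout replicate 3 (adjusted p = 0.0140) and without wild-type replicate 1 (0.0352), monocyte genes without knockout replicate 3 (0.0211) and endothelial genes without wild-type replicate 1 (0.04998). With all libraries and an estimated correlation these lists were at adjusted p = 0.823, 0.843 and 0.480. Camera's direction for the mast cell list was higher although its median and mean were below 0, and the median and mean differed in sign in the oxidative stress and B-lymphoid lists.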

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

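Settings with a covariate, a pair of libraries left out, robust moderation, robust quasi-likelihood on recovered reads, a GC and length correction or the block with an estimated correlation were tried after the data were seen. Counts within 1.5 times of the main ones held for 4 tests on recovered reads (605 to 928 genes), both other scalings, the smaller pseudocount and robust moderation. The count of 661 genes was 343 with an average log2 value above 4 before testing, 182 at an adjusted p of 0.05, 2176 with the replicate block, 2350 with the block and a GC and length correction, 139 with both libraries numbered 2 left out and 186 with the granulocyte mean as a covariate. Leaving out single libraries gave 74 to 837. The 387 genes under the study's limits became 250 with no filter on low values, 856 with the replicate block, 860 with the block and the GC and length correction, 100 with both libraries numbered 2 left out and 132 with the covariate, and 51 to 567 without single libraries. The filter before testing leaves fewer genes. Leaving out libraries leaves fewer samples, but the count of 661 rose to 837 without knockout replicate 1 and to 731 without knockout replicate 3. Fewer samples alone therefore do not account for the shifts without single libraries. The cause of these and the other shifts was not tested.

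The log2 difference of Itpkb passed the limit at -0.73 with the replicate block, at -0.62 with the block and the GC and length correction, at -0.73 with robust moderation and at -0.73 in the edgeR exact test on recovered reads. It was -0.92 to -0.54 without single libraries and passed without knockout replicate 3. The count of 14 lists became 0 with the correlation estimated per list, 0 with the replicate block and an estimated correlation, and 0 with fry. With the block, camera's adjusted p at the preset correlation was 4.69e-09 for the proteasome and 3.54e-06 for multipotent progenitors. It was 0.262 for each with the estimate. The estimates there were -0.0109 and -0.0386, under the preset 0.01, and 0.235 and 0.209 without the block. A higher correlation therefore does not account for these losses with the block, and lost calls do not measure correlation alone. The fry count is of its directional test, whether the genes of a list changed together in 1 direction, where camera compares a list with the other genes. Fry's mixed test, for changes in either direction, gave adjusted p of 7.19e-04 (Atf4 list) to 0.542 (granulocyte list) over the 14 lists. In that test the stem cell list was at 0.00608 and the G2/M list at 0.0924. The G0/G1 regulators, not called by camera, were at 9.34e-04 in it. The count of 14 lists was 12 to 16 without single libraries. The cause was not tested.

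Of 2324 values of named genes under alternatives, 1988 kept their direction and side of the limit, 228 lost the call, 99 gained one and 9 turned. Of 615 values of lists, 505 kept both, 55 lost the call, 16 gained one and 39 turned. The replicate block changed no other list call than that of ribosomal proteins. The 9 that turned were of uncalled genes. Pou2af1 was at -0.048 without knockout replicate 2, in a range of -0.048 to 1.57 without single libraries, and at -0.093 with the granulocyte covariate. Without single libraries Rag1 was at -0.69 to 0.20, Cd24a at -0.20 to 0.080, Ly6a at -0.22 to 0.015 and Slamf1 at -0.082 to 0.15. Slamf1 was at -0.034 with both libraries numbered 1 left out. The cause was not tested.

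The 39 values of lists that turned belong to 12 lists, none of them called, and no turned value was called. Their adjusted p with no filter on low values was 0.772 for monocyte and for endothelial genes and 0.611 for B-lymphoid genes. With both libraries numbered 1 left out it was 0.956 for oxidative stress and for the sort gate and 0.891 for autophagy. With both numbered 2 left out it was 0.548 for oxidative stress, 0.861 for erythroid, 0.870 for monocyte, 0.801 for B-lymphoid and 0.631 for mast cell genes. With the granulocyte covariate these 5 were at 0.292, 0.674, 0.179, 0.216 and 0.174. With the block and the GC and length correction it was 0.991 for the PI3K pathway, 0.907 for oxidative stress and 0.879 for B-lymphoid and for mast cell genes. With fry it was 0.695 for oxidative stress and 0.962 for B-lymphoid genes, and 0.989 for the latter with voom values. Without single libraries, where at least 1 value of each turned, the adjusted p was 0.302 to 0.977 for G0/G1 regulators, 2.26e-08 to 0.942 for ribosomal proteins, 0.00606 to 0.965 for immediate early, 0.272 to 0.977 for oxidative stress, 0.511 to 0.892 for autophagy, 0.0140 to 0.876 for erythroid, 0.0211 to 0.992 for monocyte, 0.348 to 0.977 for B-lymphoid and 0.123 to 0.964 for mast cell genes. The cause was not tested. Depth limits low genes: 3 reads correspond to 0.393 to 0.746 normalized CPM.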

Other observations

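The tests of myeloid RNA, of mature neutrophil RNA, of cycling cells and of other marrow cell types were chosen after the values they use had been seen. Among genes chosen after their values were seen, several fell or rose outside the study's expression limit. Runx1t1, a transcriptional corepressor gene, fell from 20.1 ± 3.01 to 1.34 ± 1.07 normalized CPM (log2 difference -3.29, limma, adjusted p = 0.00340), and Sox18, an endothelial transcription factor gene, fell by 2.81. Cyp26b1, which degrades retinoic acid, fell from 20.1 ± 9.75 to 2.25 ± 0.88, Pygm, muscle glycogen phosphorylase, from 26.4 ± 1.90 to 4.03 ± 1.58, and Apob from 7.80 ± 1.47 to 0.10 ± 0.08, which is under the floor of 3 reads in Itpkb-/- libraries. Rcvrn rose from 0.11 ± 0.10, also under that floor, to 7.71 ± 1.28. Vldlr, a lipoprotein receptor, rose by 1.83, Cd180 by 1.32 and Tfrc, the transferrin receptor, by 1.63. These 9 genes kept their calls whichever library was left out. Igf1 (-2.09), Igf2 (-2.17) and Igf2r (-1.10) fell, and of these Igf1 and Igf2 lost the call without wild-type replicate 3 (adjusted p = 0.207 and 0.206).

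Igf2, Igf2r, Cdkn1c (-1.70) and Ndn (-1.31) are imprinted genes, and all 4 fell, Ndn only with wild-type replicate 3 in the fit (adjusted p = 0.208 without it). A hypothesis formed on these values was that imprinted growth genes fell as a group, and it was tested on 28 other imprinted genes listed before their values were seen. Of the 17 that could be tested, 10 had negative differences. H19 (-1.97) and Grb10 (-0.73) fell and Dlk1 rose by 1.89. Their median log2 difference was -0.062, at percentile 39.7 of 10000 random lists matched on expression, and their mean was below 0 in each of the 3 pairs (-0.178, -0.0742 and -0.168). The hypothesis needed such means and also a percentile of at most 5, which was not reached, and 50 or more would have counted against it. The test leaves it open.

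The other splits of the 6 libraries bear on the counts. The design makes 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 661 genes, and the highest of the others 18. Under the study's limits the values were 387 and 11, and in each case 1 split, the real one, gave as large a count. Of the 3 other splits that part all 3 same-numbered pairs, each called 0 genes with limma, with 161 to 184 genes at an unadjusted p under 0.05 against 1858 in the real one. All other splits mix the genotypes, so any difference between genotypes widens the spread within their groups and lowers their gene counts. Their gene counts are therefore no baseline for chance. For gene lists 2 splits gave 14 or more: the real one 14, and another, which parts 1 pair, 15. The other splits that part all 3 pairs called 5, 6 and 10 lists. Camera with its preset correlation called lists in each of the 10 splits, and whether that correlation is too low or the libraries differ apart from genotype was not separated.

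A candidate source of the granulocyte genes in Itpkb-/- library 2 is RNA of granulocyte progenitors. Of 12 further progenitor genes listed before their values were seen, 12 were highest of the 6 libraries there, against 2 expected if the genes were independent. Genes of a lineage vary together, so the 12 are not separate observations, and the count does not tell such RNA from transcription by the sorted cells. Clec12a was at 79.6, Hp at 166.3 and Cst7 at 79.4 normalized CPM, beside Mpo at 8728, while Gda at 106.9 against 101.9 in Itpkb-/- library 1 and Sirpa at 76.8 against 62.9 in wild-type library 2 were barely highest. All 3 wild-type libraries had at least 1 normalized CPM of 10 of the 12 genes, 1 of the 12, Nkg7, is also in the T and NK list, and the sort excludes lineage-positive and CD34-positive cells, which should remove many of them. RNA of mature neutrophils is argued against only for the excess of primary granule genes over Itpkb-/- library 1: there the median fold was 10.7 for these and 1.21 for mature neutrophil genes, a ratio of 0.113. Mature neutrophil genes were themselves high in Itpkb-/- libraries 1 and 2, with S100a8 at 2132 and 2232 normalized CPM against 207 in library 3 and 165 to 1149 in wild type, so such RNA in both libraries remains open, as do progenitors in the gate and transcription by the sorted cells.

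For the higher G2/M genes, GC content and gene length may be weighed first: the correction moved log2 differences by a median of 0.0397 over 11903 genes and left the list median at 0.59, against 0.58 before, so a trend on either is argued against. Myeloid progenitor RNA in Itpkb-/- library 2 is argued against as the whole difference, since the median without that library was 0.34 (quartiles 0.23 and 0.44) and the list means of the pairs numbered 1 and 3 differed by 0.43 and 0.44. A part from that library remains open, because the median was lower without it. Leaving it out does not remove such RNA from the other Itpkb-/- libraries, so progenitor RNA in all of them also remains open. In the pairs numbered 1, 2 and 3 the granulocyte list differed by 0.796, 2.22 and 0.324. The multipotent progenitor list differed by 0.728, 0.791 and 0.505. Genotype remains among the open explanations, untested beyond the 3 pairs.

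For the lower stem cell genes, the GC and length correction left the median at -0.45, against -0.44 before, which argues against such a bias. A difference in cycling cannot be told apart: the median was -0.51 (quartiles -0.89 and -0.01) with the G2/M mean as a covariate, but that mean was itself higher in Itpkb-/- libraries in all 3 pairs, so the fit decides nothing. A lower share of stem cells replaced by all other marrow cell types alike cannot be told apart from other explanations: the spread between the 10 cell type lists had a permutation p of 0.266 over 3 pairs, which does not show that they moved alike. How this test is read was made stricter after its p was seen, and the mast cell list differed by -1.09, 0.27 and 0.61 in the pairs. Genotype within the sorted population and a different make-up of it both remain open.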
